A study of Bos indicus with 9 samples.

How the data were processed

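The samples were corpora lutea of crossbred Nelore cows (Bos indicus, 2 to 5 years old), collected at slaughter on day 6 after ovulation. Per the labels, 3 animals served as controls whose ovulation was synchronised with a progesterone device and estradiol benzoate. A further 3 animals received 400 IU of equine chorionic gonadotropin (eCG) on day 8 of the synchronisation and form the stimulated group. The last 3 received 2000 IU on day 4 and form the superovulated group. Total RNA of each animal was labelled as biotinylated cRNA and hybridised to 1 Affymetrix bovine array, without pooling. Dose and day of eCG changed together between the treated groups, so the comparison of these groups does not separate them.

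The deposited value table holds 24128 probe sets on 9 arrays, 112 of them array controls. Its deposited values are in no standard unit, since each number has lost its decimal mark and stands as a run of digits. The mark was put back from the values themselves. A run that starts with 0 or with 2 to 9 has 1 possible place for the mark, given a scanner limit of 16 on the log2 scale. A run that starts with 1 can be read as 1.x or as 1x.x, unless the second reading would reach that limit. Runs open in this way made up 15.5% of cells. In 19509 probe sets no cell was open, and in 1563 the other arrays of the probe set settled it. Probe sets with open runs on all 9 arrays were settled by their spread between arrays, which differs between dim and bright probe sets, at a posterior probability of 0.95. This placed 2973 as 1x.x and 19 as 1.x, with 1.7 wrong readings expected. All 62 ribosomal protein probe sets with 9 open runs were read as bright. A further 64 probe sets, 63 of them not controls, stayed undecided and were left out, which leaves 23953 tested probe sets. The recovered values run from 0.85 to 15.36. That range is why they are read here as log2 signals, as was assumed before the data were examined. The log base, the summarisation of probes and the normalisation between arrays are not given in the sources used here. Array medians lie between 4.18 and 4.25, and upper quartiles between 8.28 and 8.36. No further normalisation was applied. An array carries no read depth, and the number of arrays limits the precision.

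Gene symbols came from the array's probe table. Of the non-control probe sets 13292 carry 1 symbol, 86 carry several and 10638 carry none. Of the 9155 distinct symbols 8550 also stand in the RefSeq gene table of the Bos indicus assembly NIAB-ARS_B.indTharparkar_mat_pri_1.0, used here for names alone. No coordinates are given, since the probe table and that table were not matched by position. Where a gene has several probe sets, the 1 with the highest mean over the 9 arrays stands for it, which gives 9127 genes.

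Each probe set was fitted with limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on all 9 arrays, with 1 mean per group and 6 residual degrees of freedom. Tests were 2-sided and adjusted by Benjamini-Hochberg over the 23953 probe sets. A probe set with an adjusted p under 0.05 counts as passing. A moderated F test asked for any difference among the 3 groups. The same steps were tested on simulated data with the group sizes of stimulated against control. There 72% of 100 probe sets changed by a log2 fold of 1 were called, 88% of 100 changed by a log2 fold of 2, and 6 unchanged ones. That simulation drew probe sets independently and changed both sets of 100 at once, which eases the adjustment. Its shares do not show what would be found where few probe sets change. Standard errors (SE) of fold changes come from the moderated fit, and means per group are given with the standard deviation (SD).

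A set of 32 gene lists of pathways, luteal functions and cell types was tested with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists within a comparison. A list was called at an adjusted p under 0.05. Camera with an estimated correlation and fry, in its directional and mixed forms, were run beside it. Camera compares a list with all other genes, so a list can be called whose mean change is close to 0. Group means of a list were also compared with exact permutation tests, 2-sided, which cannot go below 0.1 with 3 animals against 3. The difference between the 3' and 5' control probe sets of 6 cattle transcripts served as a sign of RNA quality.

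The groups, the tests, the gene lists and the rule for named genes were set before the data were examined. The rule takes, per comparison and direction, up to 10 passing genes whose groups do not overlap, ranked by log2 fold change. Where fewer than 5 pass, the genes with the smallest p fill the direction up to 5 and are described as not passing. It adds up to 4 members of each list with the smallest p in that comparison. It also adds LHCGR, STAR, CYP11A1, HSD3B1, VEGFA, KDR, FLT1, PTGFR, PGR, OXT, INHBA and FST. Genes named outside this rule are marked where they appear.

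The labels number the animals of each group 1 to 3 and do not say whether equal numbers share a day or a batch. For arrays of equal number, the deviations from their group means were correlated across probe sets. Between stimulated and superovulated arrays these correlations were 0.16 to 0.38, above 0.1 for all 3 pairs. Equal numbers were therefore treated as possible pairs in this comparison, and a fit with the number as a replicate block is given beside the results it changes. Deviations from a group mean of 3 sum to 0, so some matching of arrays between groups correlates positively even without pairs. The correlations therefore cannot decide whether equal numbers share a day or a batch. Some fits with that block had been seen before this check was made.

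The alternatives were quantile normalisation, a shift of each array to the same median, removal of the dimmest probe sets up to the lower tertile or up to the median, an intensity trend with robust eBayes, array weights, a fit on the 6 arrays compared, a replicate block, other thresholds, the mean of all probe sets of a gene, and leaving out each array in turn. Added after the data were seen were the undecided runs at their likelier reading and a fit on probe sets with no open run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.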

Results

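Luteal gene expression was measured on 9 arrays, 1 per cow, in 3 groups of 3 animals. Control cows were synchronised without eCG, a placental gonadotropin of the mare that acts in cattle like both follicle-stimulating and luteinising hormone. Stimulated cows received 400 IU and superovulated cows 2000 IU. All corpora lutea, the progesterone-secreting glands that form from ovulated follicles, were taken on day 6 after ovulation. Signals are log2 values. Correlations of signal across probe sets were 0.988 to 0.994 between arrays of the same group and 0.986 to 0.994 between arrays of different groups. Signals of different probe sets do not rank expression, so genes are compared between groups only. STAR, which carries cholesterol into mitochondria, had 14.76 ± 0.11 in control, 14.79 ± 0.02 in stimulated and 14.67 ± 0.13 in superovulated corpora lutea (mean ± SD, n = 3). CYP11A1, which makes pregnenolone, had 14.16 ± 0.11, 14.16 ± 0.13 and 14.07 ± 0.17 (SD, n = 3). HSD3B1, which converts pregnenolone to progesterone, had 14.49 ± 0.07, 14.45 ± 0.08 and 14.32 ± 0.09 (SD, n = 3).

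Over the 3 groups, 1 of 23953 probe sets passed the moderated F test, that of PRSS2 (adjusted p = 0.00190), and 1841 had an unadjusted p under 0.05 in this limma test. The count was 2 without stimulated replicate 3 and 2 without superovulated replicate 3.

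The comparison of stimulated with control corpora lutea asks how luteal gene expression differed after the lower dose of eCG, given on day 8. PRSS2, which encodes a trypsinogen and has 1 probe set on the array, was lower in all 3 stimulated animals, at 2.31 ± 0.17 against 8.18 ± 0.40 in control (SD, n = 3). The log2 fold change was -5.87 (SE 0.33, adjusted p = 0.00305). Genes induced by interferon were higher as a group, with a mean log2 fold change of 0.85 over 31 genes and 30 of them positive. Markers of macrophages and other myeloid cells were also higher, by a mean of 0.73 over 36 genes, while genes of the cell cycle were lower by a mean of -0.47 over 68 genes. The calls of these lists rest on the preset correlation, and their adjusted p values with an estimated correlation were 0.557, 0.655 and 0.876.

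PRSS2 was the 1 probe set that passed, and 0 passed as higher. In stimulated animals its signal lay in the range of the dimmest probe sets, with 13.5% of all probe sets below it, so the size of the fold depends on the array's background. The assignment of this probe set to PRSS2 is that of the probe table and was not checked against a genome. An unadjusted p under 0.05 was found for 883 probe sets with higher and 653 with lower signal in stimulated animals. The groups did not overlap for 11.5% of probe sets, against 10% by chance. Without stimulated replicate 3 no probe set passed, and PRSS2 had an adjusted p of 0.0501. The count was 2 without control replicate 2 or superovulated replicate 3.

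The genes with the smallest p after PRSS2 did not pass. Among those with lower signal, S100A9, a subunit of the neutrophil protein calprotectin, had a log2 fold change of -3.57 (SE 0.61, adjusted p = 0.369), and a second probe set of it had -1.78. FSTL3, a secreted protein that binds activin, had -1.40 (SE 0.19, adjusted p = 0.237). MMP9, a gelatinase, had -1.42 (SE 0.21, adjusted p = 0.254), and PIGK, part of the enzyme that attaches lipid anchors to proteins, had -0.69 (SE 0.11, adjusted p = 0.353). Among those with higher signal, CERT1, which moves ceramide from the endoplasmic reticulum to the Golgi, had 0.76 (SE 0.08, adjusted p = 0.0796). ACSM1 and ACSF2, both acyl-CoA synthetases, had 2.17 (SE 0.30, adjusted p = 0.237) and 0.92 (SE 0.13, adjusted p = 0.254). FCGR3A, an immunoglobulin receptor, had 1.08 (SE 0.14, adjusted p = 0.200). Each of these genes had 3 stimulated animals on the same side of all 3 controls.

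**Figure D1:**
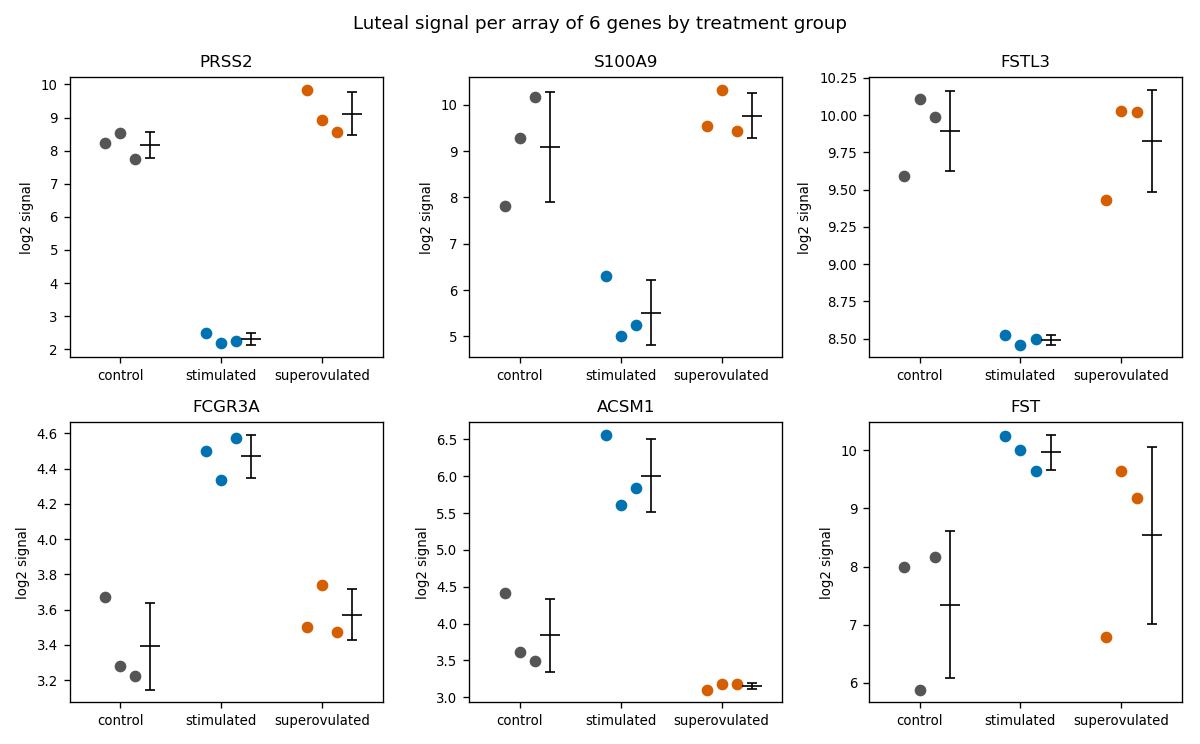
Log2 signal per array of 6 genes in control, stimulated and superovulated corpora lutea (points: animals; bars: mean and SD, n = 3; each axis has its own range). PRSS2 lies between 2.18 and 2.51 in the stimulated animals and between 7.76 and 9.83 in the other 6; the other 5 genes did not pass the adjusted test.

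The interferon-stimulated list was called with an adjusted p of 1.22e-15, and with 0.557 under an estimated correlation. Of its 31 genes 19 were higher and 0 lower at an unadjusted p under 0.05. Adjusted over all probe sets 0 passed, and adjusted over the list alone 7 passed, all higher. GBP5, an interferon-induced GTPase, had a log2 fold change of 3.05 (SE 0.73), and PARP9 had 1.13 (SE 0.27). UBA7, which activates the ubiquitin-like protein ISG15, had 1.07 (SE 0.19), and IRF9, a subunit of the transcription factor that interferon activates, had 1.07 (SE 0.26). The list's mean per array was 7.05 ± 0.23 in stimulated and 6.21 ± 0.36 in control animals (SD, n = 3) and did not overlap (exact permutation p = 0.1, the smallest possible).

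The macrophage and myeloid list was called with an adjusted p of 6.33e-11 (0.655 with an estimated correlation), and its means per array did not overlap. At an unadjusted p under 0.05, 17 of its 36 genes were higher and 2 lower. Adjusted over all probe sets 0 passed, and adjusted over the list alone 11 passed, 9 of them higher. LYZ2, a lysozyme, had 1.95 (SE 0.36) and AIF1, a cytoplasmic protein of macrophages, 1.73 (SE 0.36). With the mean of all probe sets LYZ2 had 0.52. The 2 lower genes were S100A9 and S100A8, the latter named after its value was seen. Both encode proteins abundant in neutrophils, for which no list was tested. Of the 36 genes 6 had negative values in all.

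Other cell type lists had smaller shifts. MHC class II and antigen presentation genes had a mean of 0.33 over 19 genes (adjusted p = 0.000171, and 0.557 with an estimated correlation), with BOLA-DMB at 1.18 (SE 0.29) and TAPBP, a chaperone of class I molecules, at 0.27 (SE 0.08). Without control replicate 3 the list's mean was 0.21. Adjusted over the list alone 0 of them passed. T and NK cell markers had a mean of 0.27 over 31 genes (adjusted p = 0.000458, and 0.876 with an estimated correlation), with 4 genes higher and 0 lower at an unadjusted p under 0.05. NKG7 had 0.70 (SE 0.18), and the T cell coreceptor CD8A 1.23 (SE 0.47). With the mean of all probe sets NKG7 had 0.35, and without stimulated replicate 1 CD8A had 0.67. GNLY, a lytic protein of killer cells, had 1.83 (SE 0.65). The list's mean signal was 3.30 against 3.03 in control, near the dim end of the array, and without the probe sets of lowest mean its log2 fold change was 0.44. Without stimulated replicate 1 the mean of this list was 0.12 and its adjusted p 0.109. Endothelial markers had a mean of 0.15 over 25 genes (adjusted p = 0.0147, and 0.876 with an estimated correlation), and the call ended without control replicate 1 or 3 or stimulated replicate 2, with adjusted p values of 0.340, 0.185 and 0.720 and means of 0.0041, 0.10 and 0.0040. Without control replicate 2 the mean was 0.35 and without stimulated replicate 3 it was 0.29. On probe sets with no open digit run it was 0.24.

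Cell cycle and DNA replication genes were called as lower (adjusted p = 1.79e-05, and 0.876 with an estimated correlation), with 63 of 68 genes negative and 1 lower at an unadjusted p under 0.05. CDKN2C, an inhibitor of cyclin-dependent kinases, had -0.65 (SE 0.17). The list's mean per array was 8.38 in control replicate 2 and 7.27 and 7.57 in the other controls. Without control replicate 2 its mean log2 fold change was -0.15 and its adjusted p 0.291.

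Metabolic lists were called with means near 0. Glycolysis and hypoxia genes had -0.08 over 35 genes (adjusted p = 0.00603, and 0.655 with an estimated correlation). Of these HK1, PKM, PFKL and TPI1, all glycolytic enzymes, had log2 fold changes of -0.32, -0.63, -0.44 and -0.30, and PFKL had -0.29 without control replicate 3. The list's mean was -0.14 without stimulated replicate 2, -0.05 without control replicate 2 and -0.04 without stimulated replicate 3, where its adjusted p was 0.0647. On probe sets with no digit run open to 2 readings it was -0.20. Proteasome genes had -0.04, oxidative phosphorylation genes -0.06, cholesterol synthesis and uptake genes 0.11 and cytosolic ribosomal protein genes 0.03. Their adjusted p values were 0.00404, 0.00603, 0.0231 and 0.0480, and 0.876 for each with an estimated correlation. Each of these calls ended when some single arrays were left out. For proteasome genes this was stimulated replicate 2 (adjusted p = 0.141, mean -0.0001), and on probe sets with no open digit run their mean was 0.0838 (0.786). Without stimulated replicate 1 the proteasome mean was -0.0864. For oxidative phosphorylation genes it was control replicates 1 and 3 and stimulated replicate 2 (0.146, 0.220 and 0.639, means -0.0397, -0.0271 and -0.0119), while the mean was -0.11 without control replicate 2 and -0.12 without stimulated replicate 1. For cholesterol genes it was control replicates 2 and 3 and stimulated replicates 1 and 3 (0.191, 0.286, 0.0709 and 0.151), with a mean of 0.0626 without control replicate 3 and 0.19 without control replicate 1. The ribosomal call held without stimulated replicate 1 and ended without any other single array (0.0583 to 0.330). It also ended under quantile normalisation (0.0764) and without the probe sets of lowest mean (0.132). The mean was 0.0113 without stimulated replicate 3, and leaving out a superovulated array does not change it.

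The remaining 21 lists were not called. Their means ran from -0.19 for pericyte and smooth muscle markers to 0.21 for complement and coagulation genes, and the smallest adjusted p was 0.0873. Progesterone synthesis genes had a mean of -0.12 over 19 genes (adjusted p = 0.817) and angiogenic factors and receptors 0.07 over 51 genes (adjusted p = 0.728). Of the 12 genes followed in every comparison 0 passed. FST, which encodes the activin-binding protein follistatin, had the highest log2 fold change at 2.62 (SE 0.83, adjusted p = 0.698), and its signal was 9.97 ± 0.30 in stimulated against 7.35 ± 1.27 in control animals (SD, n = 3). VEGFA had the lowest at -0.19. The 3' to 5' difference of the cyclophilin control was higher in stimulated than in control animals by 0.13 (exact permutation p = 0.1, the smallest possible), and that of the GAPDH control by 0.04 (exact permutation p = 0.1).

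**Figure D2:**
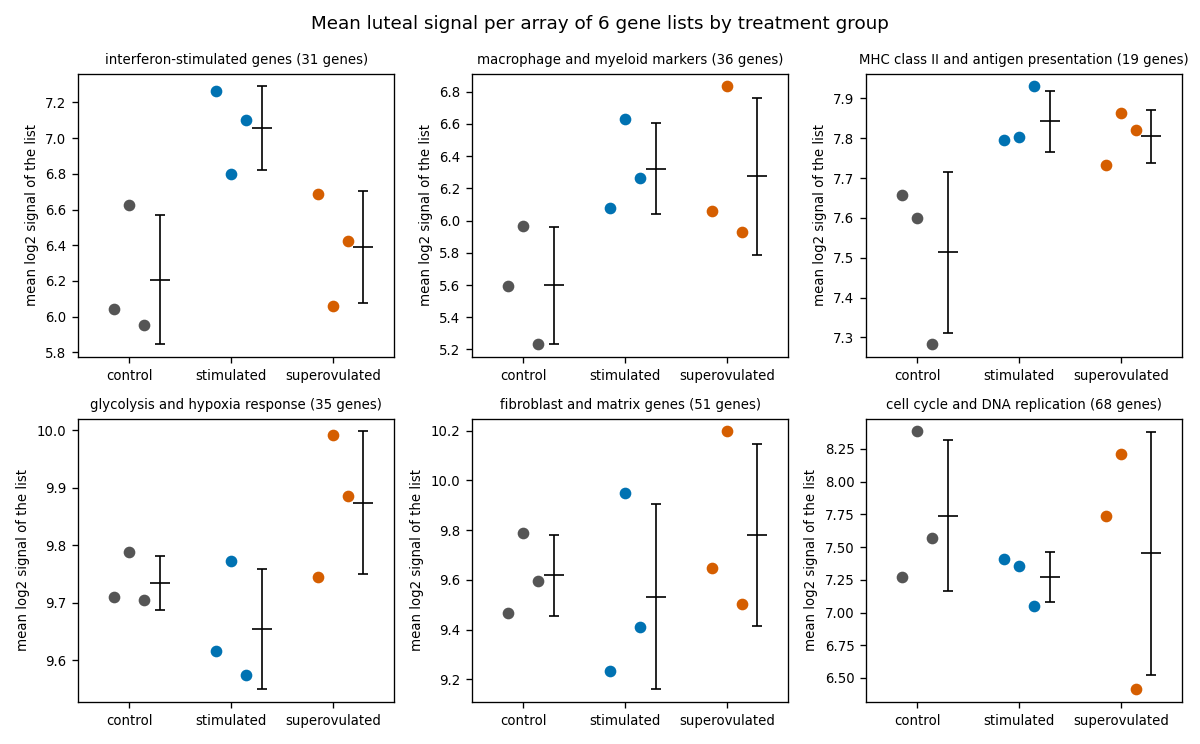
Mean log2 signal per array of 6 gene lists in the 3 groups (points: animals; bars: mean and SD of the 3 animals; each axis has its own range). Interferon-stimulated genes lie between 6.80 and 7.26 in stimulated animals and between 5.95 and 6.69 in the other 6, and the cell cycle list spreads from 6.41 to 8.21 within the superovulated group.

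The comparison of superovulated with control corpora lutea asks the same of the higher dose, given on day 4. No single gene passed in either direction. Macrophage and myeloid markers were higher as a group, with a mean log2 fold change of 0.68 over 36 genes, 34 of them positive. LYZ2 had 1.79 (SE 0.36) and AIF1 1.63 (SE 0.36), each without passing (adjusted p = 0.638 for both). With the mean of all probe sets LYZ2 had 0.46. Without superovulated replicate 2 the mean of the list was 0.40. The list was called with an adjusted p of 3.31e-09, and with 0.933 under an estimated correlation. At an unadjusted p under 0.05, 10 of its genes were higher and 0 lower. Adjusted over all probe sets 0 of them passed, and adjusted over the list alone 2 passed, both higher. Its mean per array was 6.27 ± 0.49 against 5.60 ± 0.37 in control (SD, n = 3), and the groups overlapped (exact permutation p = 0.2).

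The limma test called 0 of 23953 probe sets, with 621 higher and 863 lower at an unadjusted p under 0.05. The groups did not overlap for 10.9% of probe sets, against 10% by chance. Without stimulated replicate 3, which takes part through the pooled spread, 1 probe set passed with lower signal. It carries no gene symbol here.

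The genes with the smallest p in this comparison had adjusted p values of 0.488 to 0.638. With higher signal, ATF3, a transcription factor induced by stress, had 0.75 (SE 0.11), TUFT1 0.69 (SE 0.12) and the signalling adaptor DOK2 0.56 (SE 0.09). CERT1 and CCNC, which encodes cyclin C, had 0.42 each (SE 0.08 and 0.07). With lower signal, NCEH1, a hydrolase of cholesterol esters, had a signal of 6.25 ± 0.18 against 7.25 ± 0.33 in control (SD, n = 3), and a second probe set of it had a log2 fold change of -3.25. CBY1 had -0.58 (SE 0.11), the histone methyltransferase NSD3 -0.56 (SE 0.10), PTHLH, a hormone related to parathyroid hormone, -0.45 (SE 0.08) and CENATAC -0.42 (SE 0.08). Other probe sets of NSD3 had values from -0.40 to 0.63, and those of DOK2 lay between -0.06 and 0.10 and that of CENATAC at 0.02. VEGFA, the main angiogenic growth factor, had -0.61 (SE 0.13, adjusted p = 0.638) at a signal of 11.48 ± 0.18 against 12.09 ± 0.24 in control (SD, n = 3). A dimmer probe set of VEGFA had -0.02. FLT1, a receptor of VEGFA, had -0.51 (SE 0.20, adjusted p = 0.801), with -0.32 without control replicate 2 and -0.18 for the mean of its probe sets. Of the 12 genes followed throughout 0 passed.

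A further 2 lists were called, both as lower. Oxidative phosphorylation genes had a mean of -0.07 over 78 genes (adjusted p = 0.000154, and 0.933 with an estimated correlation), and the call ended without control replicate 3 or superovulated replicate 2 (adjusted p = 0.150 and 0.742, means -0.0329 and -0.0065). Its mean was -0.12 without control replicate 2 or superovulated replicate 3. Cell cycle genes had -0.29 over 68 genes (adjusted p = 0.00438, and 0.933 with an estimated correlation), with CDKN2C at -0.52 (SE 0.17), or -0.33 without superovulated replicate 3. The list's direction turned without single animals, to 0.03 without control replicate 2 and to 0.23 without superovulated replicate 3. The remaining 29 lists had means from -0.09 for progesterone synthesis genes to 0.35 for markers of surface epithelium and oviduct, and the smallest adjusted p was 0.128. Among them MHC class II and antigen presentation genes had a mean of 0.29 over 19 genes (adjusted p = 0.133, and 0.933 with an estimated correlation). Their means per array, 7.81 ± 0.07 against 7.51 ± 0.20 in control animals (SD, n = 3), did not overlap (exact permutation p = 0.1, the smallest possible). The epithelial markers stood at 4.38 in superovulated replicate 2 and between 3.23 and 3.57 in the other 8 animals. Without control replicate 2 the count of called lists was 7, without superovulated replicate 1 it was 5 and without superovulated replicate 3 it was 11. The 3' to 5' difference of the cyclophilin control was higher by 0.11 than in control animals, that of the eIF-4E control by 0.15 and that of the glutathione S-transferase control by 0.34 (exact permutation p = 0.1 for each).

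Changes against control in the treated groups share the same 3 control animals. Across 9127 genes, which are not independent replicates, the log2 fold changes of the treated groups correlated at 0.42. Simulated groups without any change that shared the controls gave 0.50 on average (SD 0.0212, 100 simulations), and a covariance of 0.0373 against 0.0378 observed. The observed correlation lay below all 100 simulations, which ran from 0.446 to 0.549. The share of genes with the same sign was 62.3%, also below the lowest simulated share of 65.4%. The covariance lay within its simulated range of 0.0325 to 0.0432. The simulation drew each gene independently and left out any pairing of arrays of equal number. Genes vary together on real arrays, so the simulated ranges are too narrow. A value outside them does not decide whether the treated groups share changes.

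The comparison of superovulated with stimulated corpora lutea sets the eCG regimens against each other. PRSS2 was higher in all 3 superovulated animals, at 9.11 ± 0.65 against 2.31 ± 0.17 (SD, n = 3), a log2 fold change of 6.80 (SE 0.33, adjusted p = 0.000984) whose size depends on the array's background. Interferon-stimulated genes were lower as a group, with a mean log2 fold change of -0.66 over 31 genes, 29 of them negative. Genes of glycolysis and the hypoxia response were higher, with a mean of 0.22 over 35 genes. The adjusted p values of these lists with an estimated correlation were 0.993 and 0.958.

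PRSS2 was the 1 probe set that passed, and 0 passed as lower. At an unadjusted p under 0.05, 973 probe sets were higher and 1340 lower in superovulated animals, and the groups did not overlap for 13.5%, against 10% by chance. With the replicate number as a block PRSS2 had an adjusted p of 0.00469. The count was 2 without stimulated replicate 3 or superovulated replicate 3, and 3 without superovulated replicate 1.

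Further genes with small p did not pass. ACSM1 had -2.85 (SE 0.30, adjusted p = 0.0796), and where 1 value per gene was tested its adjusted p was 0.0410 at the same fold change, since it has 1 probe set and fewer tests were made, within a range of 0.0410 to 0.255 over its alternatives. ITCH, a ubiquitin ligase, had -0.84 (SE 0.10, adjusted p = 0.0968), ACSF2 -0.94 (SE 0.13, adjusted p = 0.165) and NSD3 -0.77 (SE 0.10, adjusted p = 0.133). Other probe sets of NSD3 had values from -0.61 to 0.03, and the mean of all was -0.31. The chemokine CCL3 had -0.47 (SE 0.07, adjusted p = 0.214), and its other probe sets had -0.90 and 0.05. The last of these had a mean signal of 1.85, close to the array's background. On the higher side S100A9 had 4.25 (SE 0.61, adjusted p = 0.175) and FSTL3 1.33 (SE 0.19, adjusted p = 0.170). A second probe set of S100A9 had 2.28. The receptor phosphatase PTPRU had 0.51 (SE 0.07, adjusted p = 0.165) and BZW1 0.52 (SE 0.08, adjusted p = 0.214). A second probe set of BZW1 had 0.19. VEGFA had -0.42 (SE 0.13, adjusted p = 0.444) and FLT1 -0.73 (SE 0.20, adjusted p = 0.378). The dimmer probe set of VEGFA had 0.25, and the means of all probe sets were -0.08 for VEGFA and -0.29 for FLT1. Of the 12 genes followed throughout 0 passed.

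The interferon-stimulated list was called with an adjusted p of 2.38e-09 (0.993 with an estimated correlation). At an unadjusted p under 0.05, 14 of its genes were lower and 0 higher. Adjusted over all probe sets 0 passed, and adjusted over the list alone 7 passed, all lower. HERC5, the main ligase for ISG15, had -0.84 (SE 0.19), IFI44L -0.91 (SE 0.23), PARP9 -0.99 (SE 0.27) and IRF9 -0.97 (SE 0.26). The list's mean per array was 6.39 ± 0.32 against 7.05 ± 0.23 in stimulated animals (SD, n = 3), and the groups did not overlap (exact permutation p = 0.1, the smallest possible). T and NK cell markers had a mean of -0.21 (adjusted p = 0.0275, and 0.993 with an estimated correlation), with GNLY at -1.74 (SE 0.65). Without the probe sets of lowest mean the list's mean was -0.35. The call ended without stimulated replicate 1 (mean -0.06) or superovulated replicate 3 (mean -0.16). MHC class II and antigen presentation genes had a mean of -0.04 (adjusted p = 0.0425, and 0.993 with an estimated correlation). Their median was -0.17, with 16 of 19 genes negative. Their means per array were 7.81 ± 0.07 against 7.84 ± 0.08 in stimulated animals (SD, n = 3) and overlapped (exact permutation p = 0.6). The mean log2 fold change was 0.01 without stimulated replicate 3. The call ended without any one of stimulated replicates 1 and 2 and superovulated replicates 1 and 3 (adjusted p = 0.0861 to 0.170). It also ended without the probe sets of lowest mean (0.0555). The mean was -0.17 with the undecided digit runs at their likelier reading, and 0.0608 on probe sets with no open digit run, where the call ended (0.239).

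The glycolysis list was called with an adjusted p of 0.000264 (0.958 with an estimated correlation), and fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.0151. Its directional test gave 0.162. At an unadjusted p under 0.05, 8 of its genes were higher and 1 lower. Adjusted over all probe sets 0 passed, and adjusted over the list alone 4 passed, all higher. These were HK1 with 0.46 (SE 0.07), the pyruvate kinase PKM with 1.10 (SE 0.22), PFKL with 0.85 (SE 0.19) and TPI1 with 0.42 (SE 0.10). Its mean per array was 9.87 ± 0.12 against 9.65 ± 0.10 in stimulated animals (SD, n = 3), and the groups overlapped (exact permutation p = 0.2). On probe sets with no digit run open to 2 readings the list's mean was 0.48.

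Stromal lists were called as higher in superovulated animals, while their means per array overlapped between the groups. For pericyte and smooth muscle markers these were 7.97 ± 0.33 against 7.61 ± 0.32 in stimulated animals (SD, n = 3, exact permutation p = 0.2). For fibroblast and matrix genes they were 9.78 ± 0.37 against 9.53 ± 0.37 (SD, n = 3, exact permutation p = 0.5). Pericyte and smooth muscle markers had a mean log2 fold change of 0.36 over 19 genes (adjusted p = 0.0138, and 0.993 with an estimated correlation). Fibroblast and matrix genes had 0.25 over 51 genes (adjusted p = 0.00996, and 0.993 with an estimated correlation). Among these COL15A1 had 0.57 (SE 0.20) and the microfibril protein MFAP5 1.71 (SE 0.68), or 1.05 without superovulated replicate 2, and 0 passed adjusted over the list alone. Superovulated replicate 2 had the highest mean of the fibroblast list at 10.20, against 9.23 to 9.95 in the other 8 animals. Without it the mean log2 fold change was 0.04 for the fibroblast and 0.26 for the pericyte list (adjusted p = 0.864 and 0.122). Both calls also ended without stimulated replicate 1 or 3, and the pericyte call without superovulated replicate 1 (mean 0.27), with the fibroblast mean at 0.10 without stimulated replicate 1. Without superovulated replicate 3 the means were 0.39 and 0.55, and without stimulated replicate 2 they were 0.46 and 0.55. Within the 3 pairs of equal number the superovulated array was higher in 3 of 3 for both lists, by 0.09 to 0.41 for the fibroblast and 0.14 to 0.75 for the pericyte list. Leaving out 1 array breaks its pair. The labels do not give these pairs, which were inferred from correlations among the same arrays. The pair differences and the fit with a block are therefore no independent support for these lists. With the replicate number as a block both lists had an adjusted p of 0.000777. On probe sets with no digit run open to 2 readings both calls ended (adjusted p = 0.136 for the pericyte and 0.270 for the fibroblast list).

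Genes of protein folding in the endoplasmic reticulum had a mean of 0.10 (adjusted p = 0.0444), cholesterol genes -0.10 (adjusted p = 0.0489) and cytosolic ribosomal protein genes -0.03 (adjusted p = 0.0332), each with 0.993 under an estimated correlation. The ribosomal call ended with the replicate number as a block (adjusted p = 0.0666). It also ended without stimulated replicate 3 or superovulated replicate 3 (0.196 and 0.315), under quantile normalisation (0.306) and without the probe sets of lowest mean (0.0581). The cholesterol mean was 0.02 without superovulated replicate 2, and its call ended without control replicate 2 or stimulated replicate 1 or 3 (0.0768, 0.117 and 0.212) and without the probe sets of lowest mean (0.0578). The folding call ended without control replicates 2 or 3, stimulated replicates 1 or 2 or superovulated replicate 2 (adjusted p = 0.0518 to 0.704), under quantile normalisation (0.0805) and on probe sets with no open digit run (0.108), with means from 0.0181 without superovulated replicate 2 to 0.17 without superovulated replicate 3. The remaining 23 lists had means from -0.18 for B and plasma cell markers to 0.28 for markers of surface epithelium and oviduct, with 0.0535 as the smallest adjusted p. Mean, median and test had the same sign for each called list in all 3 comparisons, and differed in sign for 10, 4 and 10 of the lists not called. The count of called lists was 5 without stimulated replicate 1 or 3. The 3' to 5' difference of the glutathione S-transferase control was higher by 0.35 in superovulated than in stimulated animals (exact permutation p = 0.1).

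**Figure D3:**
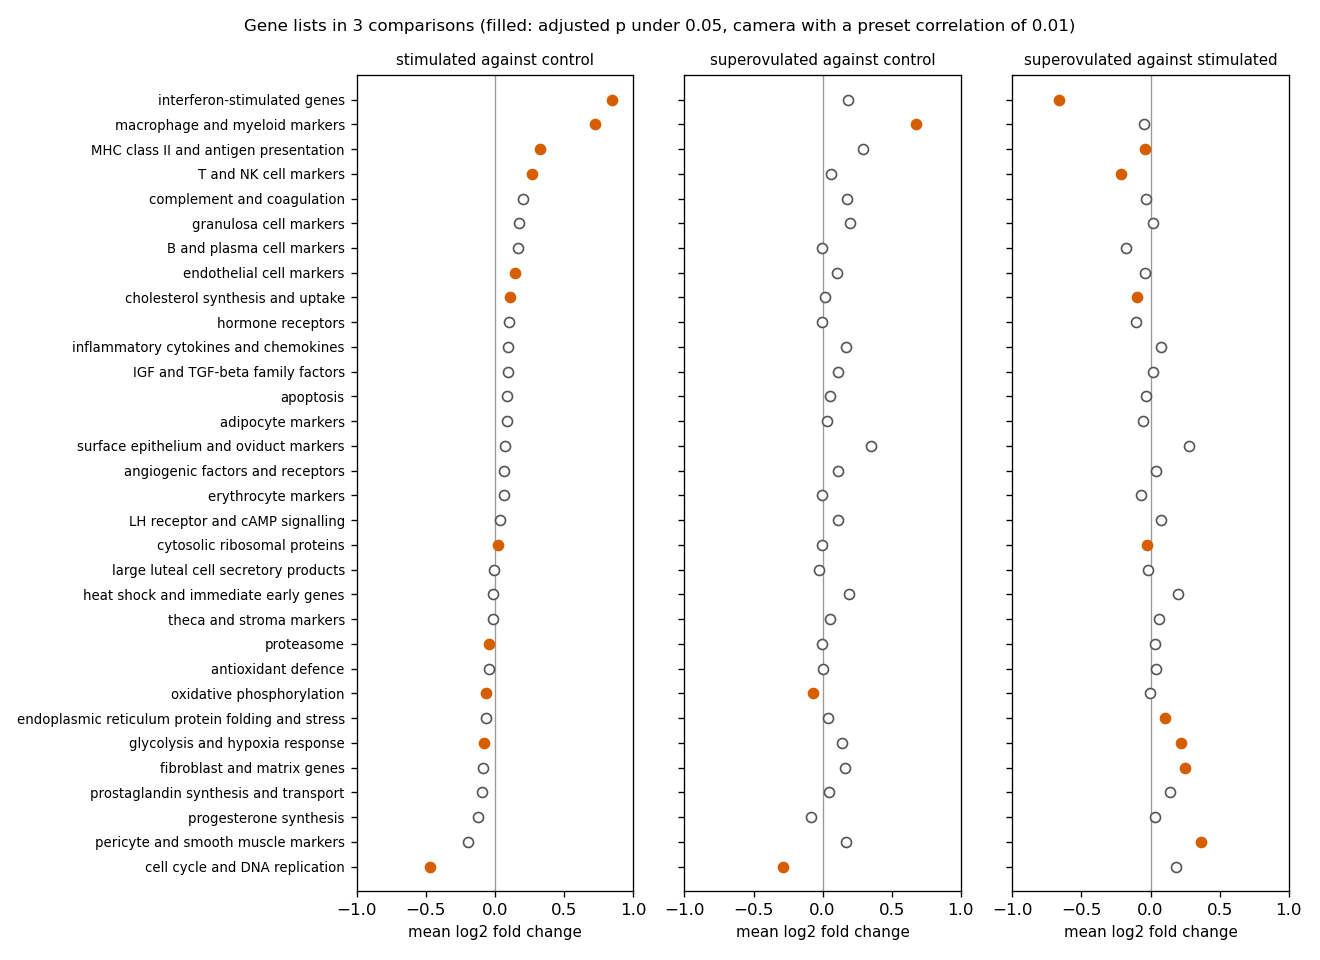
Mean log2 fold change of the 32 gene lists in the 3 comparisons (filled points: lists called by camera with a preset correlation of 0.01). Interferon-stimulated genes lie at 0.85 for stimulated against control and at -0.66 for superovulated against stimulated; with an estimated correlation 0 lists were called in any comparison, where 2, 0 and 1 had an unadjusted p under 0.05.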

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

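The tests of a misread decimal mark and of the macrophage share, and the form of the test of an all-or-none difference, were chosen only after the results they measure had been seen.

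PRSS2 differed between the eCG regimens by a log2 fold change of 6.80 between superovulated and stimulated animals, in a test of the difference itself. The stimulated signals, 2.18 to 2.51, lie near the array's background, which sets the size of this fold. Its probe set has 0 digit runs that can be read in more than 1 way, which argues against a misread decimal mark. Exocrine pancreas tissue in the control and superovulated samples would bring its other abundant transcripts. The median log2 fold change of the 13 measured of 22 pancreas markers was 0.0012 for stimulated against control, with values from -0.14 to 0.76. Their median signal in control was 2.63. CPA1, CELA3B and PNLIP stood at 2.48, 2.63 and 2.71 in control and PLA2G1B at 4.61, while AMY2B alone exceeded 6, at 7.54. These markers are named outside the rule for named genes. What stays open is an all-or-none difference between animals, such as a sequence variant under the probes, that may have fallen on the groups by chance. Besides PRSS2, 1 probe set parted 3 arrays from the other 6 by at least 3 on the log2 scale, and 0.0357 such probe sets are expected to part a whole group by chance. The 95% Poisson interval of that value, 9e-04 to 0.199, spans the bound of 0.05 set for the test, so it decides nothing. A first test, of a variant through other probe sets of PRSS2, decided nothing, since there are 0 of them, and an effect of the regimen itself was not tested apart from the animals.

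Interferon-stimulated genes differed between the regimens by a mean log2 fold change of -0.66, in a test of the difference itself with the preset correlation (adjusted p = 0.993 with an estimated correlation). A single animal does not carry the higher level in the stimulated group, since the lowest mean without 1 stimulated array was 0.74. A larger share of macrophages in the stimulated samples may add to it and cannot be told apart from it. The macrophage list differed between superovulated and stimulated arrays by -0.0488 (standard error 0.325, and 0.156 between pairs of equal number), against -0.66 for the interferon list (0.227 and 0.0479). In the 3 pairs the macrophage differences were -0.02, 0.20 and -0.33, the last of them 0.5 of the interferon difference in the same pair, -0.68. Without S100A8 and S100A9, left out after their values were seen, the macrophage list differed by -0.25 (paired standard error 0.161), or 37.5% of the interferon difference, between the bounds of 25% and 50% set for the test. The regimen, in which dose and day changed together, remains an untested explanation.

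Between superovulated and stimulated animals, tests of the difference with the preset correlation also picked out mean log2 fold changes of -0.10 for cholesterol genes, -0.21 for T and NK cell markers, -0.037 for MHC class II genes, -0.027 for cytosolic ribosomal protein genes and 0.22 for glycolysis genes. With an estimated correlation the adjusted p was 0.958 for glycolysis genes and 0.993 for the others, and the cholesterol mean was 0.02 without superovulated replicate 2. The pericyte, fibroblast and protein folding lists were called in that comparison too (0.36, 0.25 and 0.10), but not against control, and with an estimated correlation each had an adjusted p of 0.993. Against control, MHC class II genes had means of 0.33 in stimulated and 0.29 in superovulated animals, called in stimulated animals alone.

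Other groupings of the same arrays were fitted as well. With 3 animals against 3 there are 10 splits, too few for a share under 0.05. For stimulated against control 1 probe set passed in the real grouping and at most 0 in another, so 1 of the 10 splits gave as many. The lists called were 11 in the real grouping and at most 13 in another, with 2 of 10 splits as large. For superovulated against control 0 probe sets passed against at most 1 in another split, and since every split has at least 0, its 10 of 10 tests nothing. The lists called there were 3 against at most 12, with 10 of 10 splits as large. Such list counts can reflect a structure among the animals or the low preset correlation, which were not separated. For superovulated against stimulated, 1 probe set passed against at most 0, with 1 of 10 splits as large, and 9 lists against at most 14, with 5 of 10. Of these splits 4 part the 3 pairs of equal number, again too few for a share under 0.05. The others among the 4 passed 0 probe sets and called 5 to 6 lists. They had at most 860 probe sets at an unadjusted p under 0.05 in the limma test, against 2313 in the real grouping. Among all 10 splits of this comparison, 1 other split had 2453 such probe sets, more than the real grouping. Splits that part equal numbers showed a like gap in stimulated against control (at most 898 against 1536). So did superovulated against control (at most 852 against 1484), where 0 probe sets passed. The pairs were inferred from the same arrays, so these gaps are no independent support for a difference. For the F test over the 3 groups, 9 of 100 drawn splits of the 9 arrays gave as many probe sets as the real 1, the highest 2. Chance is therefore not excluded for that count. These splits were drawn without regard to replicate numbers, so a possible pairing of equal numbers was not taken into account.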

How the results depend on the processing

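The likelier reading of the undecided digit runs and the restriction to probe sets with no open run were chosen after seeing the data. PRSS2 kept its direction and an adjusted p under 0.05 under every alternative except, against control, without stimulated replicate 3 (range 0.000708 to 0.0501, and 0.000197 to 0.0291 between the treated groups). Across the 64 gene values followed through the alternatives, which leave out VEGFA in stimulated against control, 0 reversed. Among them ACSM1 alone gained a pass, in superovulated against stimulated with 1 value per gene, at an unchanged fold change and fewer tests. An estimated correlation counts the variation that a list's genes share, and weakens a call where it exceeds the preset 0.01. It did so in every called list, with estimates from 0.06 for glycolysis genes to 0.67 for cell cycle genes.

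Passing probe sets (1, 0 and 1 for stimulated against control, superovulated against control and superovulated against stimulated, and 1 in the F test) came to 6, 0, 8 and 1 at an adjusted p under 0.10. At an unadjusted p under 0.05 with a fold of at least 1.5 they came to 420, 369, 636 and 520. Superovulated against stimulated gave 2 under quantile normalisation, the median shift, array weights and no open run, with BPNT2 added. BPNT2 and FABP5 were named after their values were seen. Superovulated against control gave 1 on its 6 arrays alone. The replicate block gave 3 in stimulated against control, with FABP5 and a probe set without a symbol added, where only 2 of 3 pairs of equal number correlated above 0.1 (-0.04 to 0.28), and 0 in superovulated against control (0.08 to 0.35, also 2 of 3). Leaving out 1 array gave 0 to 2, 0 to 1, 1 to 3 and 1 to 2.

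Called lists (11, 3 and 9, in the order of comparisons above) fell to 0, 0 and 0 with an estimated correlation and with directional fry, while mixed fry called 0, 0 and 5, with glycolysis and ribosomal genes the only ones of the 9 among these 5. Without the probe sets of lowest mean the last comparison had 6, losing the cholesterol, MHC class II and ribosomal calls. On probe sets with no open run, 7 and 4 were called in the first and last, with the cholesterol, oxidative phosphorylation and ribosomal lists too small to be tested. With the replicate block the ribosomal call of the first ended (adjusted p = 0.135). Leaving out 1 array gave 7 to 11, 2 to 11 and 5 to 9. On probe sets with no open run only the dimmer members of a list remain. There the proteasome mean turned to 0.0838 in stimulated against control and the MHC class II mean to 0.0608 in superovulated against stimulated. Leaving out 1 array moved the cell cycle mean in superovulated against control from -0.67 to 0.23, and in superovulated against stimulated the cholesterol mean from -0.17 to 0.0204 and the MHC class II mean from -0.0661 to 0.0067. The correlation of treated-group changes (0.42) was 0.50 in simulations without change. The pseudocount alternative was not run, since the values are logarithms already. Signals near 2, such as KDR, are close to the array's background, where changes cannot be resolved. The cause was not tested for these changes.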

Other observations

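The products that mark the mature luteal cell were measured in all 3 groups. OXT, which encodes oxytocin, had 13.67 ± 0.08 in control, 13.70 ± 0.12 in stimulated and 13.61 ± 0.29 in superovulated animals (mean ± SD, n = 3). PTGFR, the receptor of the luteolytic prostaglandin, had 13.90 ± 0.01, 13.82 ± 0.07 and 13.73 ± 0.25. Its dimmer probe sets had log2 fold changes of -0.42 and -0.25 for stimulated against control. For superovulated against control they had -0.54 and -0.26. LHCGR, the receptor that binds luteinising hormone, had 6.13 ± 0.84, 6.22 ± 0.26 and 6.56 ± 0.05. Of these genes 0 passed in any comparison, which does not show that their levels were equal.

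The first principal component held 26.7% of the variance, of which 19.1% lay between groups, and superovulated replicate 2 stood apart on it. Components 2 and 3 held 17.6% and 15.4%, of which 59.3% and 57.6% lay between groups. That animal had the highest mean of the fibroblast and matrix list (10.20), of the macrophage list (6.83) and of the surface epithelium and oviduct list (4.38).

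A hypothesis from the data is that 1 animal may carry the lower cell cycle signal of the treated groups. Without control replicate 2, 31.5% of the mean log2 fold change of stimulated against control was kept (-0.15), and the mean of superovulated against control was 0.03. That second mean moved further, to 0.23, without superovulated replicate 3, so there a treated animal may carry it as well as a control animal. The test without any 1 control array was set before its result was seen and could have left the larger part of both means in place. Control replicate 2 was picked as the array whose removal shrank the stimulated mean most, and it had the highest list mean of the controls. Without control replicates 1 and 3, 150.1% and 118.4% of the stimulated mean were kept. For the superovulated mean these shares were 181.6% and 130.0%. A difference of 1 animal is therefore a candidate explanation for this list, and no biological explanation was tested apart from it.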
